A study of Drosophila melanogaster with 15 samples.

How the data were processed

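The series is an mNET-seq study, a form of native elongating transcript sequencing, of Drosophila melanogaster embryos at stage 15, an assay that sequences RNA held by engaged RNA polymerase. Per the labels' protocols, flies were kept at 25 °C, 6000 embryos were dounced per preparation, and libraries were made with a kit for small RNA. The labels place 15 samples in 4 groups by sex and by treatment: 4 female control, 4 female MOF, 3 male control (numbered 2, 3 and 4) and 4 male MOF. Male control replicate 1 was not analysed here. The table used here is the authors' annotation of transcription units, which holds positions and gene identifiers and no read count, coverage or other measured value of any sample. The coverage tracks that the labels mention were not analysed here, so the depth of each sample is unknown, and no comparison between the 4 groups was tested. Nothing in the sources used here says whether the numbered replicates came from separate collections.

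Per the file headers, the authors wrote the annotation with rtracklayer 1.48.0. Its genome build is dm6, per the submitters' processing notes. These notes also name cutadapt 2.8, STAR 2.7.4a, SAMtools 1.20 and DESeq2 of the authors, with no role stated, and no value made by them was used here. The annotation release and the rule by which the authors joined genes into units are not given in the sources used here. The deposited units were therefore checked directly. The table holds 15991 units and 17698 genes with 34736 transcripts, and every gene stands in a single unit. In 14847 units there is 1 gene, in 1144 units there are several, and the most is 18. No unit overlaps another unit on the same strand (0 of 15991), so overlapping genes of a strand stand in a joint unit. The unit length equals end minus start plus 1 in every line.

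Gene types and current symbols were taken from a RefSeq gene table of Release 6 plus ISO1 MT, the assembly that dm6 also holds. Genes were matched on the same chromosome by current symbol (14056), FlyBase identifier (23), CG or CR number (3185) or synonym (375), which placed 17639 of the 17698 genes (99.67%). The remaining 59 kept the name in the annotation and had no gene type. Of 14802 units that hold 1 matched gene, 14690 (99.24%) had exactly the RefSeq gene's start and end coordinates. Unit bounds are thus those of the gene models, with no filter on expression that could be seen. The start of a unit is the outermost annotated start of its genes, not a start site measured in these embryos. That bears on any promoter or pausing signal read against it.

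Units on X (2399) were compared with units on the autosomal arms 2L, 2R, 3L, 3R and 4 (13449 in all), since dosage compensation in male flies concerns the X. Shares were compared with two-sided Fisher's exact tests. Lengths and gaps were compared with two-sided permutation tests of the difference of median log2 values over 100000 reassignments, for which 2e-05 is the smallest p they can give. A divergent neighbour was an opposite-strand start upstream of a unit's start at a start-to-start distance of at most 500 bp. An overlap was at least 1 bp, and a gap ran from a unit's end to the next start on the same strand. Neighbouring units are not independent and units are not biological replicates. Intervals (95%) were therefore drawn from 2000 bootstrap samples of 1 Mb blocks, 24 on X and 113 on the autosomes. For genes in joint units and for inner starts there were 112 autosomal blocks. A p-value here describes units of a single annotation, and none measures spread between embryos. Benjamini-Hochberg adjustment covered the 7 comparisons of X with the autosomes, or all 31 gene lists. In the settings restricted to some genes it covered the lists that kept any of them (26 with protein-coding genes alone, 22 with X genes alone, 30 with autosomal genes alone).

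The gene lists, the tests and the rule for naming genes were fixed before the data were examined. The rule names every member of the MSL, MSL partner, NSL, sex determination and pausing lists. It also names the longest and shortest unit of each other list, the 5 longest and 5 shortest units and the 5 closest divergent pairs on X and on the autosomes, and any member without a unit in lists of at most 15 genes. Families of genes were listed by symbol pattern, and the list of long non-coding RNA genes by the prefix lncRNA or asRNA, which gave 1946 genes of type lncRNA and 503 of type antisense RNA. A list's unit length was set against random lists of as many units (100000 draws, lists of at least 5 units), and its share on X against all other units by Fisher's exact test. No block entered the list tests, which count linked units as independent, so their p-values are too small for lists that lie in few places. Where a list gene shares a unit, the length and the start are those of the whole unit. The comparisons of genes in joint units and of inner starts, the block bootstrap and the tests of divergent starts per list were chosen after the table was seen.

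On simulated data of 15848 units with a known shift of 0.3 on the log2 scale, the X against autosome length test passed the threshold of 0.05 in 40 of 40 runs, with a mean estimate of 0.29. With a shift of 0.1 it did so in 26 of 40, and with no shift in 2 of 40. A list of 12 units shifted by 1 on the log2 scale passed in 15 of 40 runs, so short lists had limited sensitivity. These runs used p without adjustment over the lists, and adjustment can only lower that count. The simulated units were independent, unlike neighbours on the map, so these rates do not cover linked units. The distance code was checked against a direct search on a simulated chromosome. Alternatives set X against each of 2L, 2R, 3L and 3R alone (not chromosome 4 alone) or left out chromosome 4. Others were other distances and overlaps, no units under 1000 bp, protein-coding genes only, current symbols only and mean in place of median. Without units under 1000 bp, neighbours were sought again among the units kept, while protein-coding units kept all their neighbours. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.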

Results

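The study design set embryos with maternal depletion of mof by RNA interference against control embryos, in males and in females sorted apart, at stage 15. MOF is the acetyltransferase of histone H4 lysine 16 in the male-specific lethal (MSL) complex, which raises transcription of the single male X. The 15 samples comprised 4 female control, 4 female MOF, 3 male control and 4 male MOF libraries. Per-library coverage was not analysed here, so the contrasts of MOF with control and of males with females carry no values in what follows. What was measured is the map against which nascent transcription was to be read: 15991 transcription units on build dm6, of which 2399 lay on X, 13449 on the autosomes, 112 on Y and 31 in the mitochondrial genome.

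Of the 7 units of the MSL list, 3 lay on X. The mof unit spanned X from 5873840 to 5876853 on the minus strand (3014 bp, 1 transcript), and its start lay 146 bp downstream of the end of Usp30 on the same strand. roX1 and roX2 are the non-coding RNAs of the complex. The roX1 unit spanned X from 3857230 to 3862697 on the minus strand (5468 bp, 5 transcripts), began 268 bp after the end of yin, and shared 392 bp with the plus-strand unit that holds ec. The roX2 unit spanned X from 11579065 to 11580432 on the plus strand (1368 bp, 6 transcripts) and began 258 bp after the end of CG11695. The msl-2 gene encodes the subunit that limits the complex to males. Its unit, joined with mir-4971, spanned 2L from 3462218 to 3466112 (3895 bp), and its start lay 45 bp from the divergent start of ND-PDSW. The other subunits were autosomal. The msl-1 unit on 2L (18683720 to 18688800) was 5081 bp long. That of mle, the RNA helicase, on 2R (5974857 to 5980778) was 5922 bp long. The msl-3 unit on 3L (7123213 to 7125533) was 2321 bp long and had the BBS1 start 372 bp upstream. The list's median of 3895 bp was not separable from that of random lists of 7 units (permutation test, p = 0.17, adjusted p = 0.23 over 31 lists). Its share on X, 42.9% against 15.0% of other units, did not pass either (Fisher's exact test, p = 0.074, adjusted p = 0.23).

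**Figure D1:**
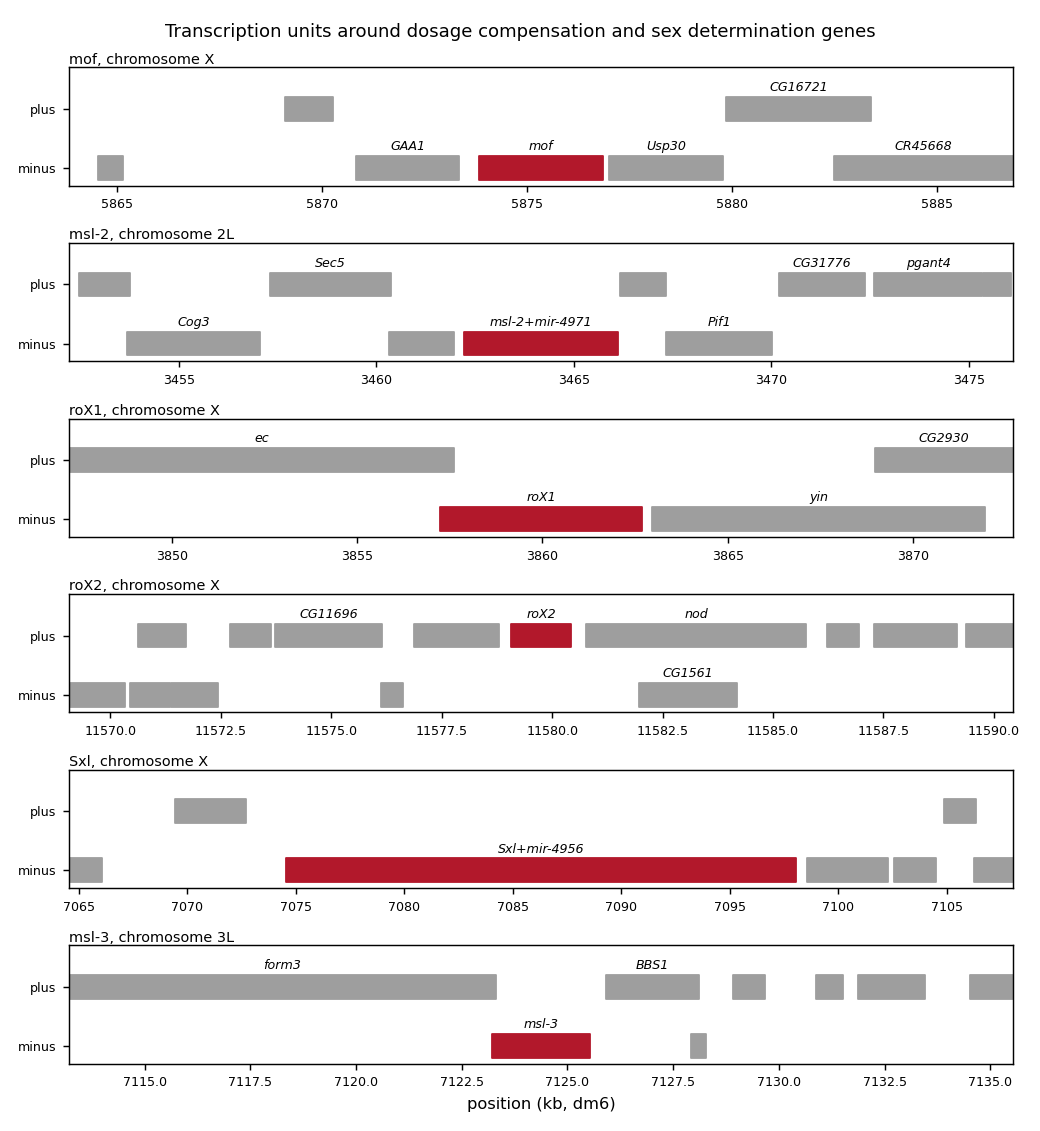
Units within 10000 bp on each side of mof, msl-2, roX1, roX2, Sxl and msl-3, by position in kb on dm6 and strand (plus above, minus below); the named unit is red, neighbouring units are grey, and short neighbours are left unlabelled. The mof start lies 146 bp from the end of Usp30 on its own strand, and the msl-2 start 45 bp from a divergent start.

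All 8 partner genes of the MSL complex lay on autosomes. Clamp, the zinc-finger protein that binds the MSL entry sites, had a unit of 3424 bp on 2L that shared 502 bp with a unit on the opposite strand. JIL-1, the histone H3 kinase, had the longest unit of the list (14442 bp), and Su(var)205, which encodes heterochromatin protein 1a, the shortest (1497 bp). Su(var)3-7 measured 5675 bp, Top2 6126 bp, su(Hw) 4135 bp, BEAF-32 2162 bp and the joint unit of Chro and CR45968 6605 bp. In the NSL complex, the second complex that holds MOF and acts at autosomal as well as X promoters, mof and wds (2238 bp) lay on X. The other members were autosomal: nsl1 (8321 bp), Rcd1 (4861 bp), MBD-R2 (4123 bp), Rcd5 (2069 bp), dgt1 (2797 bp) and Chro. Divergent starts lay within 500 bp of 4 of its 8 units (50%, against 24.3% of other units). These were Rcd1 (30 bp from pea), Rcd5 (47 bp from CG11593), Chro (105 bp from Ssl1) and wds (281 bp from CG13760).

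The sex determination list had 6 of 17 units on X (35.3%), a share that passed before but not after adjustment over the lists (Fisher's exact test, p = 0.032, adjusted p = 0.12). The list includes X-linked signal elements, which lie on X by definition, so the choice of members partly fixed that share. On X stood Sxl, the switch gene of female development, joined with mir-4956 (7074550 to 7098053, 23504 bp, 26 transcripts). The X-linked signal elements sc (1438 bp), sisA (779 bp), upd1 (3938 bp) and run (6652 bp) and the splicing factor gene snf (1260 bp) lay there too. On the autosomes, fru (131314 bp) and dsx (43086 bp), the transcription factor genes at the end of the pathway, had the longest units. They were followed by gro (8176 bp), da (5124 bp), fl(2)d (4930 bp), emc (4093 bp), dpn (3360 bp), her (2507 bp, joined with mir-2497), tra2 (2334 bp, joined with scaRNA:PsiU5-44), tra (992 bp) and ix (727 bp). The unit of sc was overlapped over its whole length by an opposite-strand unit (1438 bp), and so was that of emc (4093 bp).

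Genes of pausing and pause release had 5 of 14 units on X (35.7%, Fisher's exact test, p = 0.047, adjusted p = 0.16). These were the subunits of the pausing factor NELF encoded by NELF-B (2366 bp) and TH1 (2619 bp), the bromodomain gene fs(1)h (23629 bp), Larp7 (2109 bp) and Spt6 (7188 bp). On the autosomes were Nelf-A (5809 bp), Nelf-E (1438 bp), spt4 (584 bp), Spt5 (4416 bp), M1BP (1909 bp), Cdk9 (1665 bp), CycT (6785 bp) and Hexim (1740 bp). Trl, which encodes the GAGA factor, shared a unit of 13916 bp with CG42507 and CG33260, and its own annotated start lay 795 bp inside that unit. Opposite-strand starts lay within 500 bp of 10 of the 14 units, from 43 bp at Cdk9 to 394 bp at NELF-B. The Trl unit counts through the start of its joint unit (184 bp), and Trl's own start lies farther than 500 bp away.

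Units on X were longer than units on the autosomes. The median was 2242 bp on X and 1774 bp on the autosomes, a difference of 0.34 on the log2 scale or 1.26-fold (block bootstrap interval 0.21 to 0.46; permutation test, p = 2e-05, adjusted p = 0.00014). X had a higher median than each of 2L (1624 bp), 2R (1781 bp), 3L (1723 bp) and 3R (1888.5 bp), and a lower one than the small chromosome 4 (6955 bp, 109 units). Units over 50 kb made up 3.13% of X (75 units), against 1.60% on 3R to 1.99% on 3L among the large autosomal arms. Among units with a protein-coding gene the medians were 2679 bp on X and 2164 bp on the autosomes.

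**Figure D2:**
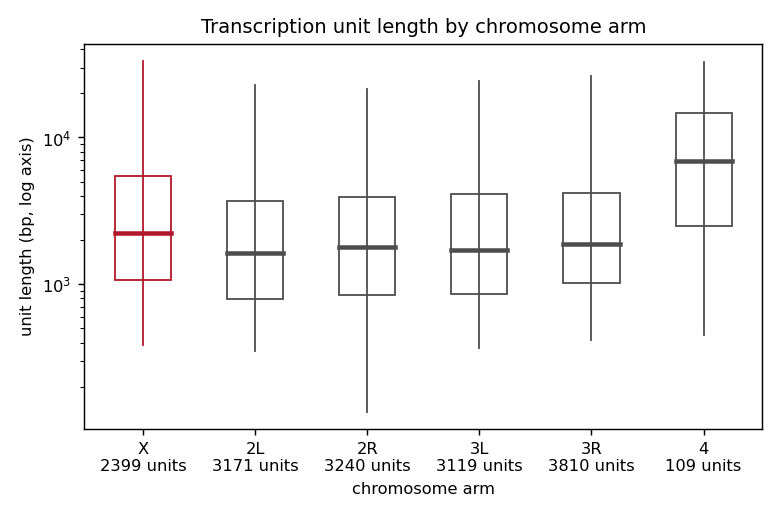
Unit length in bp (log axis) by chromosome arm; boxes span the 25th to 75th percentiles, thick lines are medians, and thin lines run from the 5th to the 95th percentile of the units of each arm. The X median of 2242 bp lies above those of 2L, 2R, 3L and 3R and below that of chromosome 4.

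The 5 longest units held more genes on X than on the autosomes, which was not tested. Among all units, 7.34% on X held several genes, against 7.06% on 2L to 7.34% on 3L among the large autosomal arms. On X, the cell adhesion gene kirre shared a unit of 394149 bp (2740384 to 3134532) with 12 other genes. The unit of Ten-a, listed first under CR43960, held 8 genes in 291517 bp, and the units that begin with CR44357 (239347 bp, 8 genes), CR32773 (223710 bp, 6 genes) and rg (169106 bp, 3 genes) followed. On the autosomes the 5 longest held 1 or 2 genes each: Myo81F on 3R (1965857 bp), Pzl on 3R (709421 bp), CG45782 on 3L (434041 bp), and CG17684 (396036 bp) and CG45781 (379081 bp) on 2R. The shortest units were small RNA genes. On X these were 3 ribosomal 2S genes or pseudogenes of 30 bp (2SrRNA-Psi:CR40677, 2SrRNA-Psi:CR45858 and 2SrRNA:CR45864), mir-9369 (62 bp) and mir-303 (70 bp). On the autosomes they were tRNA:CR32123:Psi (53 bp), a snoRNA gene on 2R (19727098 to 19727152, 55 bp), mir-9379 (57 bp), mir-9385 (63 bp) and mir-312 (66 bp).

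Joint units hide gene starts. Of protein-coding genes, 14.9% on X (324 of 2171) and 13.6% on the autosomes (1593 of 11677) shared a unit with another gene (Fisher's exact test, p = 0.11, adjusted p = 0.13). For 5.48% of protein-coding genes on X (119) and 3.73% on the autosomes (436) the gene's own start lay over 1000 bp inside its unit, a difference of 1.75 percentage points (block bootstrap interval 0.44 to 3.28; Fisher's exact test, p = 0.00027, adjusted p = 0.00093). Without the 5 longest units of X and of the autosomes the shares were 4.26% and 3.74% (Fisher's exact test, p = 0.24). This setting is lopsided, since the 5 longest held 3 to 13 genes on X and 1 or 2 on the autosomes, so it could hardly change the autosomal share. Among listed genes, Gr2a began 43361 bp inside the unit of futsch, and Or1a 35420 bp inside a unit that starts with CG3777. TwdlT began 52240 bp inside the unit of RYa-R, and Sfp87B 14389 bp inside the unit that holds svp.

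Units were spaced slightly wider on X. The median gap to the next start on the same strand was 3272 bp on X and 2846 bp on the autosomes, a difference of 0.20 on the log2 scale (block bootstrap interval 0.022 to 0.37; permutation test, p = 0.0079, adjusted p = 0.014). The difference was 0.018 (permutation test, p = 0.79) once units under 1000 bp were left out, as neighbours too. It was 0.30 (permutation test, p = 0.00036) among units with a protein-coding gene, with all neighbours kept. A divergent start within 500 bp was found for 22.6% of X units (542) and 24.8% of autosomal units (3335), a difference of -2.21 percentage points (Fisher's exact test, p = 0.020, adjusted p = 0.028). The block bootstrap interval of -5.97 to 1.57 included 0, and without units under 1000 bp the sign turned (0.64 percentage points, Fisher's exact test, p = 0.56). The closest divergent pairs on X were CG44532 with Zpr1 and mal with CG11710, each at a start-to-start distance of 2 bp. CG4593 with CG3032, HP1b with CG7246 and Dsor1 with amx followed at 6 bp. On the autosomes the distance was 1 bp for CG43982 with CR43983, CR45402 with CR45401, CG5991 with Atg6 and CG5039 with CG4730, and 2 bp for didum with dpa. Overlap with a unit on the opposite strand was recorded for 38.6% of X units and 39.5% of autosomal units (Fisher's exact test, p = 0.40), and the block bootstrap interval of the difference ran from -5.62 to 4.27 percentage points. The plus strand held 48.7% of X units, and none of the 7 arms, Y included, departed from equal strands (exact binomial tests, lowest unadjusted p = 0.17, lowest adjusted p = 0.51).

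Nearly every annotated gene had a unit: 98.3% of RefSeq genes on X (2660 of 2705) and 99.0% on the autosomes (14829 of 14979). The difference of -0.66 percentage points (Fisher's exact test, p = 0.0036, adjusted p = 0.0085) compares 2 gene annotations, not expression, and no block interval was drawn for it. It depends on name matching: with current symbols only it was 2.36 percentage points, with 80.9% of X genes and 78.5% of autosomal genes matched. Among protein-coding genes it was -0.77 percentage points (98.8% against 99.6%, Fisher's exact test, p = 3.7e-05). In 27 of the 31 lists every gene had a unit, including lists of genes used mainly in adults, such as odorant receptors (59 of 59), seminal fluid proteins (47 of 47), and yolk and chorion genes (12 of 12). The exceptions were small or non-coding RNAs: snoRNA genes (258 of 274, Fisher's exact test, adjusted p = 1.9e-06), long non-coding or antisense RNA genes, listed by symbol prefix (2381 of 2449, adjusted p = 2.9e-11), microRNA genes (257 of 260, adjusted p = 1) and snRNA genes (31 of 32, adjusted p = 1).

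Unit length separated the gene lists. Against random lists of as many units, 15 of 31 lists passed (permutation tests with Benjamini-Hochberg adjustment), 8 with longer and 7 with shorter units than the median of all units, 1822.5 bp. Linked units count as independent in these tests, and the Hox genes lay in 2 blocks of 1 Mb, the Y-linked genes in 4 and the histone genes in 1. The Y-linked male fertility genes were the longest as a list (median 51262 bp, adjusted p = 6.9e-05), from Pp1-Y1 (954 bp) to Ppr-Y (248273 bp). The Hox genes, which pattern the body axis, had a median of 30563 bp (adjusted p = 0.00012), from Dfd (10593 bp) to Antp in its joint unit with CR43252 (102976 bp). Neuronal genes had a median of 27653 bp (adjusted p = 6.9e-05), from nSyb (7405 bp) to the sodium channel gene para in its joint unit with Cnx14D (78070 bp). Of the 11 neuronal units, 4 are joint units. Hemocyte genes, from He (852 bp) to Pxn in its joint unit with CR45981 and CR45660 (29239 bp), had a median of 10809.5 bp (adjusted p = 0.012). Muscle genes, from Act87E (2393 bp) to sls (75931 bp), had a median of 10230 bp (adjusted p = 0.0021). Epidermis and trachea genes, from knk (3300 bp) to grh (41689 bp), had a median of 6604.5 bp (adjusted p = 0.027, or 0.061 against protein-coding units alone, over 26 lists). The microRNA genes (median 4220 bp, mir-9379 to mir-1010 at 162297 bp) and snoRNA genes (median 2702 bp, from 55 bp to snoRNA:Me18S-A1374 at 136204 bp) were also long. In these lists 159 of 231 and 89 of 103 units are joint units, so the lengths are mostly those of host genes.

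Short lists included the replication-dependent histone genes (median 529 bp, adjusted p = 6.9e-05), from His4:CG33907 (412 bp) to His1:CG33864 (1023 bp). The seminal fluid protein genes (median 533 bp) ranged from Sfp96F (168 bp) to Sfp87B in its joint unit (44049 bp). The cuticle protein genes (median 983 bp) ranged from Lcp65APsi (263 bp) to TwdlT in its joint unit (60956 bp). Ribosomal protein genes had a median of 1325.5 bp (adjusted p = 0.041), from RpS28a (304 bp) to RpS5a (4677 bp), which shares its unit with 14 snoRNA genes. The tRNA genes (median 73 bp, tRNA:Gly-GCC-1-1 at 71 bp to tRNA:Phe-GAA-1-3 at 129895 bp), snRNA genes (median 192 bp, snRNA:U6atac at 97 bp to snRNA:U5:38ABb at 162060 bp) and long non-coding or antisense RNA genes (median 765 bp, CR45515 at 200 bp to CR45220 at 709421 bp) were short as well. The longest unit of each is a joint unit, with Sema1a, sick and Pzl in turn, so its length is not that of the RNA gene. Genes of the initiation machinery had a median of 1779 bp (adjusted p = 0.93), from TfIIA-S (673 bp) to Trf2 (23740 bp). RNA polymerase II subunit genes had a median of 950 bp (adjusted p = 0.12), from Rpb10 (488 bp) to the largest subunit, RpII215, on X (7527 bp). Integrator genes had a median of 3413.5 bp (adjusted p = 0.15), from IntS12 (1184 bp) to IntS6 (8592 bp).

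The remaining lists did not pass for length, with adjusted p from 0.070 to 0.54. Glial genes ran from repo (3411 bp) to loco (19420 bp), germ line genes from bam (2019 bp) to AGO3 (135048 bp), and maternal patterning genes from grk (2513 bp) to cad (12405 bp). Fat body genes ran from Fbp2 in its joint unit with CG42847 (1957 bp) to apolpp (16305 bp), and heat shock genes from Hsp23 (884 bp) to Hsp83 (4091 bp). Yolk and chorion genes ran from Cp15 (586 bp) to Cp7Fb (2235 bp). Odorant receptors ran from Or59a (1198 bp) to Or1a in its joint unit (70802 bp), and gustatory receptors from Gr89a (1143 bp) to Gr2a in its joint unit (45109 bp). The partner list of MSL (median 4905 bp), the NSL (3568.5 bp), sex determination (3938 bp) and pausing (2492.5 bp) lists belong here too.

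**Figure D3:**
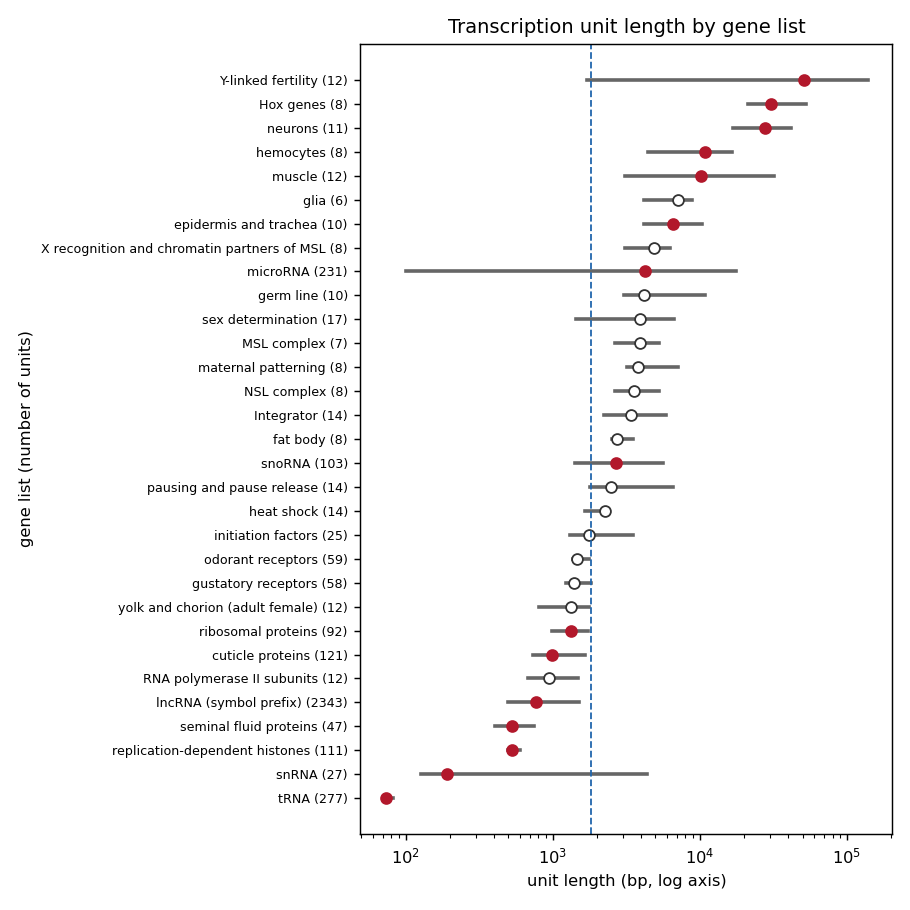
Unit length in bp (log axis) for the 31 gene lists, with the number of units in brackets; points are medians, red where the adjusted permutation p is under 0.05 and open otherwise, bars span the 25th to 75th percentiles, and the dashed line is the median of all units on the chromosome arms, 1822.5 bp. Y-linked fertility, Hox and neuronal genes have the highest medians, tRNA genes the lowest.

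The share of units on X differed from that of all other units for 7 of the 31 lists (Fisher's exact tests with Benjamini-Hochberg adjustment). These tests count linked units as independent, so p is too small where a list is clustered. The yolk and chorion genes were mostly X-linked (8 of 12 units, 66.7%, adjusted p = 0.0011), with the 8 units in 3 blocks of 1 Mb. The microRNA genes had 52 of 231 units on X (22.5%, adjusted p = 0.013), in 18 blocks. Of these 52 units, 13 lay in a single block (19168777 to 19561931), the fullest of the list, so the share rests in part on clusters. X held none of the 111 histone units, all of which lay between 21416953 and 21541681 on 2L, in 1 block, so that their adjusted p of 7.4e-07 rests on a single locus. X held none of the 47 seminal fluid protein units, which lay in 27 blocks (adjusted p = 0.0063). X held 8 of 121 cuticle protein units (6.61%, 4 of the list's 35 blocks, adjusted p = 0.031), 25 of 277 tRNA units (9.03%, 7 of 67 blocks, adjusted p = 0.020) and 12.8% of long non-coding or antisense RNA units (299, adjusted p = 0.0063). Ribosomal protein genes had 14 of 92 units on X (15.2%, adjusted p = 1), close to the 15.0% of all units.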

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

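No paired analysis was possible because no value per sample was analysed here. The tests of joint units and inner starts and the settings with the 5 longest units left out, 1 gene per unit, the gene families left out, or protein-coding units for divergent starts, overlaps and gaps were chosen after seeing the data. The difference in unit length between X and the autosomes kept its direction and passed under all 11 alternatives (0.25 to 0.47 on the log2 scale). X against chromosome 4 alone was not among the alternatives, and chromosome 4 had the higher median (6955 bp against 2242 bp). It also had a wider median gap (9546 bp against 3272 bp) and fewer divergent starts (12.8% against 22.6%) than X. The difference in gaps (0.20) was no longer past the threshold against 3L alone (0.059) or without units under 1000 bp (0.018), and was 0.30 among units with a protein-coding gene. The difference in divergent starts (-2.21 percentage points) was no longer past it against 2R (-1.08) or 3L alone (-1.90), or within 250 bp (-1.22), 1000 bp (-0.94) or 2000 bp (-1.20), and it turned without units under 1000 bp (0.64), while it was -2.66 among units with a protein-coding gene. The difference in overlap (-0.93) turned against 2L alone (0.50), with at least 10% overlap (1.78) and without units under 1000 bp (1.20), and passed against 2R alone (-2.67). The share of genes with a unit (-0.66) did not pass against 2R alone (-0.57) and turned with current symbols only (2.36), where 80.9% of X genes were matched. With protein-coding genes only it was -0.77 and passed. The share of genes in joint units (1.28) passed against 3R alone (2.23) and was -0.011 without the 5 longest units. The share with an inner start (1.75) did not pass against 2R alone (1.11) or without those units (0.52), which on X hold more genes, so that leaving them out lowers X by construction. Apart from the smaller sets of genes, units or neighbours that these settings leave, the cause was not tested. Lists past the threshold for a lower share with a unit were 2 against all other genes and 2 among autosomal genes. Among protein-coding genes, where non-coding lists drop out, there were 0. Among X genes, where they stay, there were also 0. There snoRNA genes had a share of 100%, and long non-coding or antisense RNA genes 97.1% against 98.5%. With protein-coding genes alone, adjustment covered 26 lists and not 31. Lists past the threshold for the share on X then went from 7 to 4 and for length from 15 to 12, but non-coding lists cannot enter there. For the share on X only the tRNA, microRNA and long non-coding or antisense lists were lost. The yolk and chorion, histone, seminal fluid and cuticle lists still passed. For length the snRNA, snoRNA, tRNA, microRNA and long non-coding or antisense lists dropped out. The epidermis and trachea list no longer passed for length there (adjusted p = 0.061, permutation test), while RNA polymerase II subunits (0.013), odorant receptors (0.013) and gustatory receptors (0.0053) did. Each gene stands in 1 unit and no same-strand units overlap, so alternatives on units per gene and same-strand overlap could give no other value, and overlap on the opposite strand alone is the reported value.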

Other observations

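Divergent starts divided the gene lists along lines the preceding comparisons had not tested. Within 500 bp of an opposite-strand start lay 10 of 14 units of pausing genes (71.4%), 14 of 25 of initiation factors (56.0%), 7 of 12 of RNA polymerase II subunits (58.3%) and 8 of 14 of Integrator (57.1%). All 4 lists passed against about 24.3% of other units (Fisher's exact tests, adjusted p = 0.0014, 0.0029, 0.031 and 0.024 over 31 lists). Histone genes had 88 of 111 (79.3%), all in 1 block of 1 Mb and so without an independent test, and ribosomal protein genes 37 of 92 (40.2%, adjusted p = 0.0029). The snoRNA units, mostly those of host genes, had 38.8% (adjusted p = 0.0035). Lower shares were found for odorant receptors (3 of 59, adjusted p = 0.0011), cuticle proteins (8 of 121, adjusted p = 5.8e-06), tRNA (14.8%, adjusted p = 0.00097), microRNA (15.2%, adjusted p = 0.0029) and long non-coding or antisense RNA genes (12.3%, adjusted p = 2.9e-53). None of 8 Hox, 12 muscle, 8 maternal patterning or 12 yolk and chorion units had such a neighbour, though these short lists did not pass (adjusted p = 0.33, 0.11, 0.33 and 0.11). The NSL and MSL partner lists, with 4 of 8 units each, did not pass either (Fisher's exact tests, adjusted p = 0.20 for each). Linked units, and both units of a divergent pair, count as independent in these tests, so p is too small where a list is clustered. The 121 cuticle units lay in 35 blocks of 1 Mb and the 277 tRNA units in 67. This test of divergent starts per list was chosen after the lists' shares were seen. The comparison of same-strand neighbours was also chosen after the gaps had been seen, and the other tests of explanations were fixed before their own values were computed.

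The 65 protein-coding units of the 4 transcription machinery lists, joined after their shares were seen, had a divergent start in 60.0% of cases, against 27.0% of 12975 other protein-coding units (odds ratio 4.06). Since the lists were joined for their high shares, this ratio describes the pattern and does not test it. Dense surroundings were examined as an explanation, since a median of 12 units lay within 25 kb of these starts and 10 of the others. With units grouped into 5 equal bins by that number, the pooled Mantel-Haenszel odds ratio was 3.63 (95% interval 2.17 to 6.07). The higher share of these chosen units thus remained within the bins. This ratio is no test of density, since the units were joined for that share and linked units count as independent. Grouping by unit length gave 4.11 (2.47 to 6.83), but with median lengths of 2196 and 2241 bp that grouping could hardly move the ratio and decides nothing about length. No biological explanation was tested.

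Longer units on X were set against 3 features of the annotation. Among units that hold 1 gene the difference in median log2 length was 0.32 (block bootstrap interval 0.18 to 0.46), so joining of genes is not its whole cause. Among units with a protein-coding gene it was 0.31 (0.20 to 0.42), so a lack of short non-coding units is not either. Without any family defined by a symbol pattern it was 0.25 (0.13 to 0.36), but of the 3380 units this leaves out 2486 hold no protein-coding gene. Without the ribosomal protein, histone, receptor, seminal fluid and cuticle families alone (487 units), a setting chosen after those values were seen, it was 0.30 (0.19 to 0.42), so these families are not the whole cause. Bases in introns and exons were not separated, and no biological explanation was tested, since the study's groups are of embryos and not of chromosomes.

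The lower share of divergent starts on X (ratio to the autosomes 0.91, block bootstrap interval 0.77 to 1.065) had a counterpart on the same strand. Units whose nearest same-strand unit upstream ended within 500 bp made up 18.8% on X and 21.8% on the autosomes, a ratio of 0.86 (0.74 to 0.99). That share measures the same gaps already reported as wider on X, so it decides nothing about the divergent starts, whose ratio's interval holds 1. Without units under 1000 bp the divergent difference turned (0.64 percentage points) and that in gaps was 0.018 on the log2 scale. Among units with a protein-coding gene they were -2.66 percentage points and 0.30 on the log2 scale. The first setting also removes short units as neighbours, and the second keeps all neighbours. Both differences thus depend on which units and which neighbours are counted. No biological explanation was tested.

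Some units hold very many genes. The chromatin remodeller gene dom on 2R and Arpc2 on 2L each share a unit with 17 small RNA genes (18418 and 5971 bp), and SLO2 on 2R shares 94802 bp with 16 other genes. The mod(mdg4) unit on 3R holds 15 entries (26556 bp), most of them named as its own precursors. Y had 112 units with a median of 766 bp, and 62 of its 113 genes (54.9%) were pseudogenes, against 2.58% of genes on X (69) and 1.18% on the autosomes (176), with those of rRNA and tRNA included.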
